A study of Homo sapiens with 6 samples.

How the data were processed

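Messenger RNA profiles of HEK293T cells, an established human embryonic kidney line, were analysed in 6 libraries, 3 from queuine-depleted cells (0Q) and 3 from queuine-supplemented cells (100Q). Groups and replicate numbers were taken from the submitters' sample titles. Per the labels' protocols, depleted cells were kept in medium with dialyzed serum and RNA was extracted with TRIzol. The labels disagree on the dose: the sample characteristics and the series design give 100 nM queuine, whereas the treatment protocol gives 1 µM for 24 hours. The labels name MSR-seq, a multiplexed library method, and say that each condition was grown in triplicate. They do not say whether the triplicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

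The values deposited by the authors are estimated counts per Ensembl gene, with fractions where reads fit several genes, and they are not normalized. Per the submitters' processing notes, the tools were FastQC, STAR and RSEM, with no versions given. The notes list human and mouse builds (hg38, mm39, GRCm39), and the series design gives hg38 for these libraries. The gene annotation, the strand setting of the counting, the use of molecular identifiers and any selection of polyadenylated RNA are not given in the sources used here. Estimated counts were rounded to whole numbers before testing. Total estimated counts were 7264638, 8035251 and 7604515 in 0Q replicates 1 to 3 and 5219707, 4023956 and 11398835 in 100Q replicates 1 to 3. Intervals of count ratios and floors of 3 counts cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

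Gene names, coordinates (1-based, hg38), overlaps and coding sequences came from GENCODE release 44. Of 63086 genes in the table, 62541 identifiers matched this release without their version number. The 545 unmatched identifiers held 0.129% of all counts. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom 5.36 to 14.2 over pairs within groups), so no library was taken for a second copy of another; this does not show that they are independent cultures. The labels name no batch.

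Before the data were examined, the groups, the tests, the alternatives, 34 gene lists and the rule for named genes were fixed. Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, the default expression filter (minimum count 10) and a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are 100Q minus 0Q, and levels are CPM, counts relative to the library total scaled by its TMM factor. Gene lists with at least 3 tested members were tested against all other genes with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with an estimated correlation. A list value is the mean log2 fold change of its tested members. For 6 codon sets, the longest coding sequence of each gene was used, and sets held the highest and lowest 10% of genes by the share of codons for tyrosine, histidine, asparagine and aspartate, by the share of these codons ending in C, and by the C-ending share of phenylalanine and cysteine codons as a control. Library means were compared with two-sided exact permutation tests, for which 3 libraries against 3 allow no p below 0.1.

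The rule for named genes took genes past the threshold, or, with fewer than 10 of them, the 5 genes with the smallest unadjusted p in each direction. This fallback was applied with no minimum expression and no requirement that the groups be apart. The rule also took all tested members of the lists for queuosine machinery and MHC class II, and up to 4 members of each other list with the smallest p. Within that limit, 4 members were taken from lists that passed and 2 from the others, a choice made after the list results were seen. Genes named outside the rule, apart from genes given as overlapping a named gene, members with too few counts to test and the mitochondrial genes, are said to be so where they appear, and some genes that the rule took are not reported here.

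Alternatives were RLE normalization, library size only, no filter or a stricter filter on low counts (mean count 50), the replicate number as a block, an estimated correlation, codon sets of 20% of genes, DESeq2 1.42.0, limma-voom, and leaving out each library. A correction of each library's trend with GC content and transcript length was added after the data were seen. In it, values outside a central range of the fitted genes were set to the limits of that range. The gene test was tested on simulated data drawn from the 14905 tested genes, 200 of them changed among genes with at least 5 CPM. It recovered 66% of genes changed 1.5-fold, 82% at 2-fold, 98% at 3-fold and 94% at 4-fold, with 3 wrong among 173 calls. Each simulated gene took the spread of the trend at its expression, with no spread of its own and no outlying library. Recovery in the real data may therefore be lower and wrong calls more frequent. In the simulated comparison of lists, over 14558 genes, a list of 25 genes raised 1.2-fold was called and 0 of 30 unchanged lists were. Simulated genes varied independently of each other, so this could not show how often lists of correlated genes are called wrongly. In a simulated comparison over 14545 genes with a GC trend in the 3 libraries of 100Q, 5609 calls without the correction became 0 with it. Two-sided 95% intervals are given for fold changes. Overlaps between genes were found with GenomicRanges 1.54.1.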

Results

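The series profiled the transcriptome of HEK293T cells without and with queuine, the base that mammalian cells take up and insert as queuosine into the tRNAs for tyrosine, histidine, asparagine and aspartate. Its title names codon usage, proliferation and expression of MHC class II. Depleted (0Q) and supplemented (100Q) cells gave 3 libraries each, with 7264638 to 8035251 estimated counts per library in 0Q and 4023956 to 11398835 in 100Q. Mitochondrially encoded genes took 4.98% to 6.07% of the counts of a library. The first principal component (30.9% of the variance) set 100Q replicate 2 apart and the second (22.7%) set 100Q replicate 1 apart, and neither separated the groups. The dose of queuine is 100 nM in the sample characteristics and 1 µM in the treatment protocol, so it is left open here.

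The first comparison asked which genes differ between supplemented and depleted cells. ZACN, which encodes a zinc-activated ion channel, and NEAT1, the long noncoding RNA that scaffolds nuclear paraspeckles, were higher in 100Q. NEAT1 (chromosome 11, 65422774 to 65445540) rose from 158 ± 6.0 to 228 ± 8.64 CPM (SD, n = 3 per group), and all 3 libraries of 100Q lay above those of 0Q. Its log2 fold change was 0.53 ± 0.08 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0413). ZACN (chromosome 17, 76071961 to 76083666) had 2, 0 and 0 counts in 0Q and 158, 51 and 65 in 100Q, a ratio of 149 with a counting interval of 40.9 to 1240 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00671). ZACN overlaps EXOC7 and SRP68, and its counts are uncertain because the use of strand in the counting is not stated.

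These were the 2 genes past the threshold among 14905 tested with edgeR, both higher, and no gene was called lower. At an unadjusted p under 0.05 there were 704 genes, 4.72% of those tested, with 371 higher and 333 lower. DESeq2 called 14 genes (10 higher, 4 lower), including ZACN and NEAT1, and limma-voom called 1, NEAT1. The groups did not overlap for 1579 genes (10.6%), where chance gives 10%. Among 10585 genes with a mean of at least 10 CPM, the median absolute log2 fold change was 0.094 and the median SE 0.13. The call of ZACN was lost without 0Q replicate 1, the 1 library of 0Q with counts (log2 fold change 9.86, against 7.25 in all libraries; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.108), without 0Q replicate 2 (6.70; 0.0751) or without 100Q replicate 1 (6.43; 0.140). That of NEAT1 was lost without 0Q replicates 1, 2 or 3 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.333, 0.350 and 0.0924) and without 100Q replicates 1 or 2 (0.168 and 0.169), at log2 fold changes of 0.50 to 0.56.

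The other genes with the smallest p did not pass, and most of them lie over another gene. Among those with higher values in 100Q, the noncoding ENSG00000258430, which overlaps AKT1, had 0 counts in 0Q and 80 in 100Q, at least 29-fold higher against a floor of 3 counts over the group. ENSG00000272772, annotated across SKP1 and PPP2CA, had a log2 fold change of 0.90 ± 0.15 (SE), and the pseudogene PKD1P1 had 0.67 ± 0.13. Among those with lower values, ENSG00000285053, annotated across TBCE, GGPS1 and B3GALNT2, had -1.07 ± 0.18, NUDT3, which overlaps RPS10-NUDT3, had -0.71 ± 0.14, and the ribosomal protein paralog RPL22L1 had -0.46 ± 0.11. CEMP1, which overlaps AMDHD2, had 91 counts in 0Q and 3 in 100Q, a ratio of 27.9 (9.23 to 138). The pseudogene ENSG00000249839, which overlaps CATSPER2, had -4.34 ± 0.85. Adjusted p over these 8 genes ran from 0.0896 to 0.549 (edgeR quasi-likelihood test, Benjamini-Hochberg). DESeq2 called 7 of the 8, all but NUDT3, the GC and length correction called NUDT3 and ENSG00000272772, the fit with no filter on low counts called all 8, and that without 0Q replicate 3 called ENSG00000285053. Values of the overlapping genes and pseudogenes are uncertain, since shared reads could have been split between the partners.

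**Figure D1:**
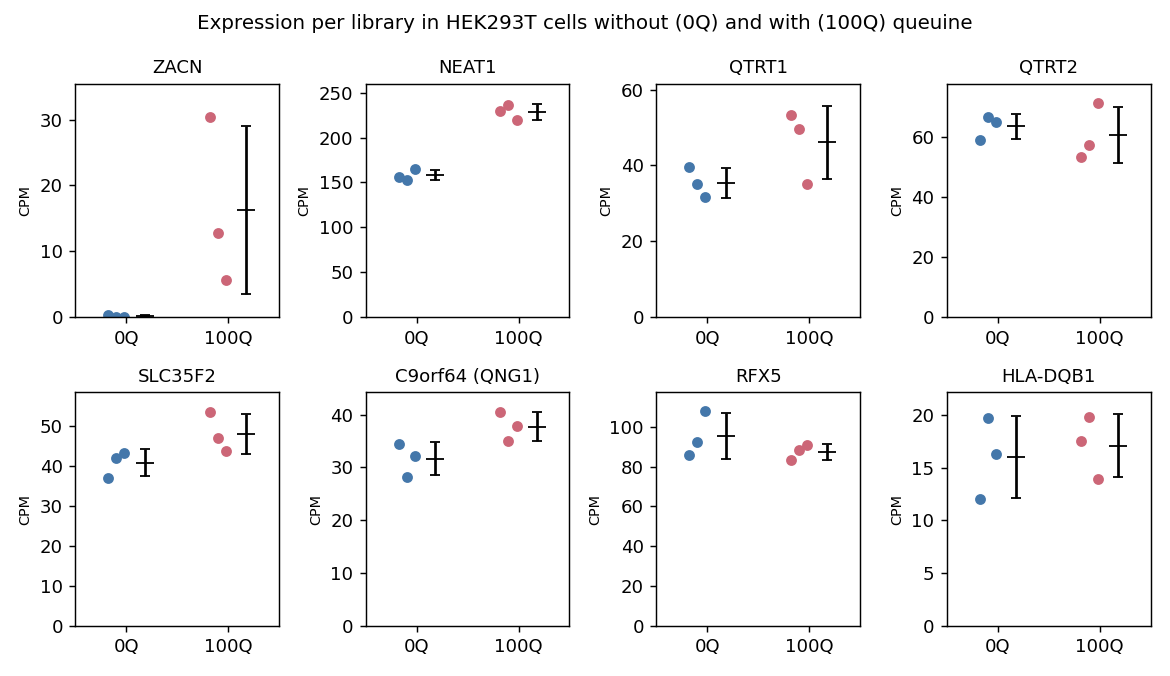
Levels of 8 genes in CPM (vertical axes, linear, from 0) in the 3 libraries of 0Q and the 3 of 100Q; dots are libraries, and the bar beside them is the mean ± SD. NEAT1 and ZACN passed the test, whereas QTRT1, QTRT2, SLC35F2, C9orf64, RFX5 and HLA-DQB1 did not.

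The genes that make and handle queuosine were examined next. QTRT1, the catalytic subunit of the transglycosylase that inserts queuine, was at 35.4 ± 3.97 CPM in 0Q and 46.1 ± 9.61 CPM in 100Q (SD, n = 3 per group), a log2 fold change of 0.36 (95% interval 0.019 to 0.70). Its partner QTRT2 had -0.05 (-0.31 to 0.21). The queuine transporter SLC35F2 had 0.23 (-0.042 to 0.50), and C9orf64 (QNG1), which releases queuine for reuse, had 0.26 (-0.029 to 0.55). The glycosyltransferases B3GNTL1 (QTGAL) and GTDC1 (QTMAN) had -0.63 ± 0.38 and 0.02 ± 0.31 (SE). None of the 6 genes passed with edgeR, DESeq2 or limma-voom, over all genes, and 0 passed with edgeR adjusted over the list alone; 1, QTRT1, had an unadjusted p under 0.05. The list had a mean log2 fold change of 0.030 and a median of 0.13 (camera, Benjamini-Hochberg adjusted p = 0.312). The stricter filter left out B3GNTL1, the member with the lowest log2 fold change. Over the other members the mean was 0.17, and the list did not pass (camera, Benjamini-Hochberg adjusted p = 0.0501). With the default filter, library means of the groups overlapped (exact permutation p = 0.9). The mean was 0.011 without 0Q replicate 2, -0.050 without 100Q replicate 1 and 0.093 without 100Q replicate 3, and the list did not pass in these fits.

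Expression of MHC class II, which presents peptides to helper T cells, was low in both groups. HLA-DQB1 was at 16 ± 3.88 CPM in 0Q and 17.1 ± 2.99 CPM in 100Q (SD, n = 3 per group), a log2 fold change of 0.07 (95% interval -0.40 to 0.54). HLA-DPA1 had 0.26 (-0.27 to 0.79), HLA-DRB1 0.64 (-0.54 to 1.82), HLA-DOA 0.18 ± 0.31, HLA-DMA -0.13 ± 0.61 and HLA-DMB -0.14 ± 0.37 (SE). The transactivator CIITA had -0.39 (-1.66 to 0.87) at 1.89 ± 0.31 and 1.39 ± 0.40 CPM, and the promoter-binding factors RFX5, RFXANK and RFXAP had -0.12 ± 0.10, -0.02 ± 0.13 and 0.00088 ± 0.18. Of 16 genes 10 were tested; 0 passed with edgeR, DESeq2 or limma-voom, 0 passed with edgeR adjusted over the list alone, and 0 had an unadjusted p under 0.05. HLA-DRA, CD74, HLA-DRB5, HLA-DPB1, HLA-DQA1 and HLA-DOB had too few counts to test. HLA-DRA had 4, 2 and 2 counts in 0Q and 2, 1 and 0 in 100Q. In the same order, CD74 had 5, 1 and 0, then 0, 0 and 2, and HLA-DRB5 14, 3 and 13, then 0, 4 and 11. HLA-DPB1 had 8, 10 and 5, then 12, 3 and 43, with most of the counts of 100Q in replicate 3. HLA-DQA1 had 4, 5 and 6, then 8, 4 and 9, and HLA-DOB 4, 9 and 14, then 4, 7 and 10. The list had a mean of 0.033 and a median of -0.0098, which differ in sign (camera, direction higher, Benjamini-Hochberg adjusted p = 0.888). The intervals of HLA-DQB1 and HLA-DPA1 exclude a 2-fold change in either direction, whereas those of HLA-DRB1 and CIITA do not, and reads of HLA genes can be shared between paralogs and alleles.

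Genes of the interferon-gamma pathway, which drives class II expression, were called lower as a set. Their mean log2 fold change was -0.25, with 7 of 9 tested members negative (camera, Benjamini-Hochberg adjusted p = 0.0327, and 0.484 with an estimated correlation). Library means of the groups overlapped (exact permutation p = 0.3). The other members had too few counts to test. GBP1, GBP2, CXCL10, IDO1 and CD274 had 0 to 3 counts in each library, and SOCS1 had 1, 2 and 1 in 0Q and 7, 0 and 10 in 100Q. IRF1 had -0.97 ± 0.40 (SE), IFNGR1 -0.20 ± 0.15 and IFNGR2 -0.13 ± 0.11; none of the 9 passed over all genes with edgeR, DESeq2 or limma-voom, or with edgeR adjusted over the list alone, and 2 had an unadjusted p under 0.05. The call was lost with the stricter filter (camera, Benjamini-Hochberg adjusted p = 0.0873, with a mean of -0.15) and without 0Q replicate 1 (0.0522), 0Q replicate 3 (0.170) or 100Q replicate 2 (0.248, with a mean of -0.14). Without 100Q replicate 3 it was kept, with a mean of -0.45. Interferon-stimulated genes had a mean of -0.20 over 18 tested members (camera, Benjamini-Hochberg adjusted p = 0.219), which was 0.0028 with the stricter filter and -0.033, -0.079 and -0.056 without 0Q replicate 2, 0Q replicate 3 or 100Q replicate 1. MHC class I genes, among them TAP2 at 0.19 ± 0.13, had 0.0071 over 12 (camera, Benjamini-Hochberg adjusted p = 0.883).

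Of 5 lists of ribosomal proteins, ribosome biogenesis, translation factors and tRNA synthetases, 4 were called lower as sets in 100Q, by small amounts, and cytosolic tRNA synthetases were not, with a mean of -0.00068 (camera, Benjamini-Hochberg adjusted p = 0.935). Cytosolic ribosomal protein genes had a mean log2 fold change of -0.074, with 69 of 79 negative (camera, Benjamini-Hochberg adjusted p = 2.8e-06; adjusted p = 0.583 with an estimated correlation). RPL21 had -0.27 ± 0.08 (SE), with 553 ± 33.9 CPM in 0Q and 459 ± 34.6 CPM in 100Q (SD, n = 3 per group), and RPL27 had -0.24 ± 0.08, RPS3A -0.19 ± 0.07 and RPL37 -0.20 ± 0.07. Mitochondrial ribosomal protein genes had -0.071, with 54 of 76 negative (camera, Benjamini-Hochberg adjusted p = 0.0106; adjusted p = 0.484 with an estimated correlation), among them MRPL40 at -0.51 ± 0.14, MRPS35 at -0.27 ± 0.10, MRPL15 at -0.25 ± 0.10 and MRPL3 at -0.18 ± 0.08. Ribosome biogenesis genes had -0.085, with 26 of 30 negative (camera, Benjamini-Hochberg adjusted p = 0.00667; adjusted p = 0.373 with an estimated correlation), among them PPAN at -0.28 ± 0.12 and RRS1 at -0.41 ± 0.19. Translation factors had -0.046, with 30 of 36 negative (camera, Benjamini-Hochberg adjusted p = 0.0327; adjusted p = 0.484 with an estimated correlation), among them EIF4B at -0.13 ± 0.08 and EIF3C at -0.14 ± 0.08. No single member of these 4 lists passed over all genes with edgeR, DESeq2 or limma-voom, or with edgeR adjusted over the list alone. At an unadjusted p under 0.05 there were 6, 6, 2 and 0 of them, all lower. Library means of the groups lay apart for ribosome biogenesis (exact permutation p = 0.1, the smallest possible). They overlapped for cytosolic and mitochondrial ribosomal proteins and translation factors (exact permutation p = 0.5, 0.2 and 0.2).

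Without 100Q replicate 3, the deepest library, the calls of cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis and translation factors were lost, with means of -0.014, -0.042, -0.068 and -0.0100 and adjusted p of 0.687, 0.441, 0.248 and 0.748 (camera, Benjamini-Hochberg). The mean of cytosolic ribosomal proteins was -0.042 without 0Q replicate 1, -0.12 without 0Q replicate 3, -0.14 without 100Q replicate 2 and -0.046 with the GC and length correction, and its call was kept in these fits. The call of mitochondrial ribosomal proteins was also lost without 0Q replicate 1 (camera, Benjamini-Hochberg adjusted p = 0.0869) and with the GC and length correction (0.105, mean -0.042). That of translation factors was lost without 0Q replicate 1 (0.0545) or 0Q replicate 2 (0.107), with library size only (0.0636, mean -0.028) and with the GC and length correction (0.195, mean -0.030; camera, Benjamini-Hochberg adjusted p).

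Cell cycle genes, which bear on proliferation, were called lower as sets at the preset correlation, and the adjusted p of both lists was 0.373 with an estimated correlation (camera, Benjamini-Hochberg). The G2/M list had a mean of -0.077, with 20 of 25 negative and all 3 library means of 100Q below those of 0Q (camera, Benjamini-Hochberg adjusted p = 0.00667; exact permutation p of the library means 0.1, the smallest possible). NUSAP1 had -0.26 ± 0.08 (SE), TOP2A -0.17 ± 0.08 and PLK1 -0.17 ± 0.08, whereas UBE2C had 0.23 ± 0.09. The G1/S and DNA replication list had -0.053, with 22 of 26 negative (camera, Benjamini-Hochberg adjusted p = 0.0327), among them PCNA at -0.17 ± 0.07, MCM4 at -0.13 ± 0.07 and PRIM1 at -0.20 ± 0.11. Replication-dependent histone genes, with H1-4 at -0.61 ± 0.18 and H2BC5 at -0.80 ± 0.34, had a mean of -0.15 over 24 tested members and did not pass (camera, Benjamini-Hochberg adjusted p = 0.0794); with the stricter filter on low counts the mean was -0.28 and the list passed (0.0139). The mean was -0.056 with the GC and length correction (0.42) and -0.089 without 100Q replicate 2 (0.245; camera, Benjamini-Hochberg adjusted p). No member of the 3 lists passed over all genes with edgeR, DESeq2 or limma-voom, or with edgeR adjusted over the list alone; at an unadjusted p under 0.05 there were 3 G2/M genes (1 of them higher), 1 G1/S gene and 3 histone genes. The G1/S call was lost without 0Q replicate 1 (camera, Benjamini-Hochberg adjusted p = 0.0946), 0Q replicate 2 (0.0929) or 100Q replicate 3 (0.364, with a mean of -0.032), and with library size only (0.0636, with a mean of -0.034). The G2/M call was kept with the GC and length correction (camera, Benjamini-Hochberg adjusted p = 0.0458), with a mean of -0.051.

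Heat shock chaperone genes were called lower as a set, with negative fold changes in 16 of 16 tested members. Their mean was -0.14 (camera, Benjamini-Hochberg adjusted p = 3.5e-05, and 0.373 with an estimated correlation). Library means of the groups overlapped for this list and for the glycolysis and hypoxia lists below (exact permutation p = 0.2, 0.2 and 0.3). HSPA8 was at 1178 ± 44.6 CPM in 0Q and 1005 ± 94.0 CPM in 100Q (SD, n = 3 per group; log2 fold change -0.23 ± 0.08, SE), and HSPE1 had -0.21 ± 0.08, STIP1 -0.16 ± 0.07 and HSP90AA1 -0.15 ± 0.07. Glycolysis genes had a mean of -0.082, with 17 of 21 negative (camera, Benjamini-Hochberg adjusted p = 0.0327; adjusted p = 0.583 with an estimated correlation), among them the glucose transporters SLC2A1 at -0.39 ± 0.15 and SLC2A3 at -0.41 ± 0.21, the enzyme PGAM1 at -0.14 ± 0.07 and, in the other direction, PFKL at 0.22 ± 0.11. Hypoxia-response genes had -0.11, with 13 of 17 negative (camera, Benjamini-Hochberg adjusted p = 0.0472; adjusted p = 0.484 with an estimated correlation), among them the mitophagy receptors BNIP3 at -0.35 ± 0.13 and BNIP3L at -0.35 ± 0.13 and the repressor MXI1 at -0.33 ± 0.12, whereas the growth factor VEGFA had 0.25 ± 0.10. No member of the 3 lists passed over all genes with edgeR, DESeq2 or limma-voom, or with edgeR adjusted over the list alone. At an unadjusted p under 0.05 there were 3 heat shock genes, 1 glycolysis gene and 6 hypoxia genes, all lower except VEGFA.

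The glycolysis call was lost without 0Q replicate 1 (camera, Benjamini-Hochberg adjusted p = 0.434, mean -0.044), 0Q replicate 2 (0.0929) or 100Q replicate 3 (0.744, mean -0.042), and with library size only (0.0517); its mean was -0.13 without 0Q replicate 3 or 100Q replicate 1, where it was kept. The hypoxia call was lost without 0Q replicate 2 (0.183, mean -0.066), 0Q replicate 3 (0.0551), 100Q replicate 2 (0.243) or 100Q replicate 3 (0.482), with library size only (0.0555, mean -0.089) and with the GC and length correction (0.10, mean -0.094; camera, Benjamini-Hochberg adjusted p); its mean was -0.18 without 100Q replicate 1, where it was kept.

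Among noncoding RNAs, the list of long RNAs, fixed as nuclear, was called higher and that of structural RNAs lower at the preset correlation. Where the long RNAs lie in these cells was not measured. The adjusted p of both lists was 0.373 with an estimated correlation (camera, Benjamini-Hochberg). The long RNAs had a mean of 0.16, with 8 of 10 positive and all 3 library means of 100Q above those of 0Q (camera, Benjamini-Hochberg adjusted p = 3.5e-05; exact permutation p of the library means 0.1, the smallest possible). NEAT1 passed over all genes, and 2 genes, NEAT1 and MALAT1, passed adjusted over the list alone. MALAT1, a nuclear speckle RNA, was at 584 ± 85.2 CPM in 0Q and 724 ± 86.0 CPM in 100Q (SD, n = 3 per group; log2 fold change 0.31 ± 0.10, SE), and SNHG1 and OIP5-AS1 had 0.16 ± 0.08 and 0.16 ± 0.09. The structural RNAs had a mean of -0.43, with 8 of 9 tested members negative (camera, Benjamini-Hochberg adjusted p = 0.0327). Their library means overlapped between the groups (exact permutation p = 0.6). RPPH1, the RNA of ribonuclease P (-0.92 ± 0.25), was the 1 member that passed adjusted over the list alone. Of the 9, 0 passed over all genes with edgeR, DESeq2 or limma-voom at the default filter (2 at an unadjusted p under 0.05). The telomerase RNA TERC had -0.97 ± 0.38, RN7SK -0.43 ± 0.33 and SNORD3B-1 -0.47 ± 0.54. RN7SK was called by edgeR with no filter on low counts (quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00090). It had -0.044 without 0Q replicate 1, -0.069 without 100Q replicate 2, -0.66 without 0Q replicate 2 and -0.85 without 100Q replicate 3. TERC had -0.58 without 0Q replicate 2. The structural call was lost without 0Q replicate 3 (camera, Benjamini-Hochberg adjusted p = 0.414), where the mean turned to 0.017, without 100Q replicate 2 (0.348) or 100Q replicate 3 (0.0807), and with the GC and length correction (0.284, with a mean of -0.34).

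**Figure D2:**
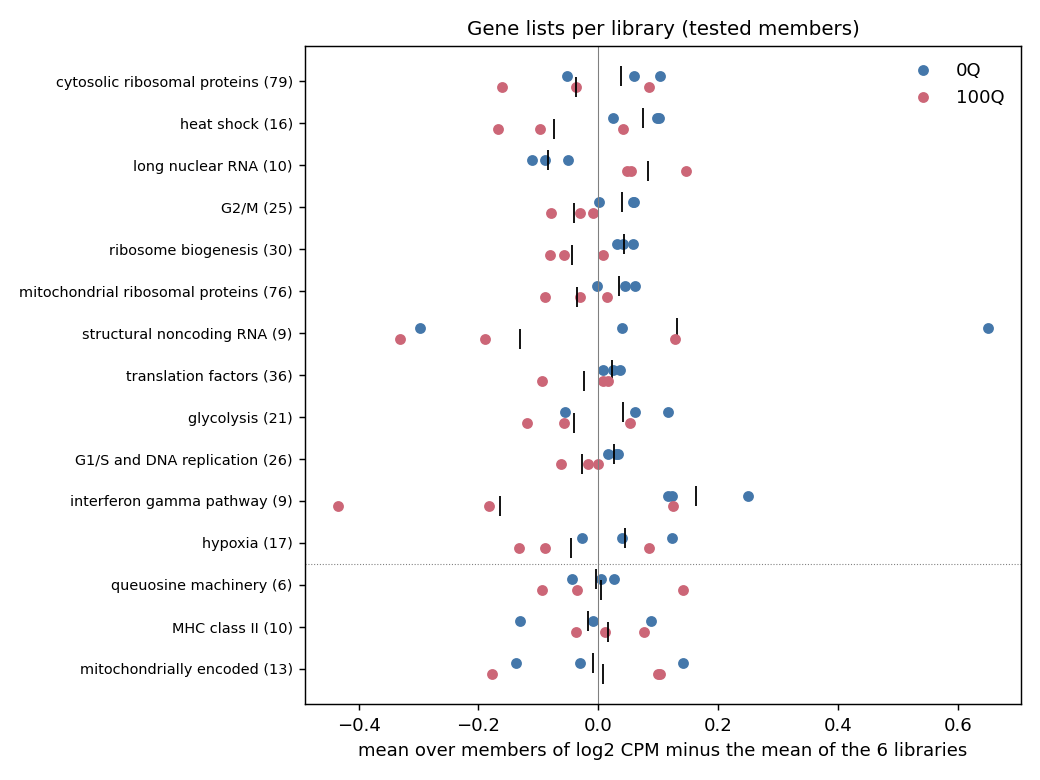
Mean over the tested members of each gene list (number in brackets) of log2 CPM minus the mean of the 6 libraries (horizontal axis); dots are libraries, ticks are group means, and lists above the dotted line passed the test. Of the lists drawn, the groups lie apart for long nuclear RNA, G2/M, ribosome biogenesis and G1/S and overlap for cytosolic ribosomal proteins, whose library means have an exact permutation p of 0.5.

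In all, 12 of 32 tested lists were called, 11 lower and 1 higher, and 0 with an estimated correlation, where the lowest adjusted p was 0.373 (camera, Benjamini-Hochberg) and 3 lists had an unadjusted p under 0.05. Library means of the groups lay apart for 7 lists, among them the uncalled histone genes, interferon-stimulated genes and p53 targets. NEAT1 was the 1 list member that passed over all genes with edgeR at the default filter, DESeq2 or limma-voom. The 20 lists not called include stress and metabolic programs. ATF4 target genes of the amino acid stress response had a mean of 0.080, with TRIB3 at 0.40 ± 0.14 and CHAC1 at 0.55 ± 0.20 (SE; camera, Benjamini-Hochberg adjusted p of the list 0.0545). They passed with library size only (camera, Benjamini-Hochberg adjusted p = 0.0474), with the stricter filter (0.0396), and without 0Q replicate 1 (0.0117, with a mean of 0.19) or 100Q replicate 1 (0.00082, with a mean of 0.13). Their mean was 0.031 without 100Q replicate 2 (camera, Benjamini-Hochberg adjusted p = 0.547) and 0.14 without 100Q replicate 3 (0.263). The adjusted p was 0.105 with the GC and length correction (camera, Benjamini-Hochberg). NRF2 targets had -0.079 (camera, Benjamini-Hochberg adjusted p = 0.0830), but 0.0013 without 100Q replicate 1 (0.363). Nuclear genes of oxidative phosphorylation had -0.038 (camera, Benjamini-Hochberg adjusted p = 0.0916), but were called lower without 0Q replicate 3 (-0.066; 0.0034) or 100Q replicate 2 (-0.079; 0.00050). Their mean was -0.011 without 0Q replicate 1, -0.0022 without 100Q replicate 3 and 0.0089 with the GC and length correction. The means were 0.12 for p53 targets (0.319; 0.075 with the stricter filter), -0.029 for secretory pathway genes (0.338; -0.0053 without 100Q replicate 3) and -0.037 for cholesterol synthesis genes (0.371; -0.062 without 100Q replicate 2 and -0.017 without 100Q replicate 3; camera, Benjamini-Hochberg adjusted p). The tRNA modification enzymes had -0.055 (0.371; -0.029 without 0Q replicate 2; camera, Benjamini-Hochberg adjusted p). The mitochondrially encoded messenger RNAs had 0.019 (camera, Benjamini-Hochberg adjusted p = 0.572), but were called higher with the GC and length correction (mean 0.13; 0.00023) and without 0Q replicate 3 (0.098; 0.0133) or 100Q replicate 1 (0.10; 0.0030). Their mean was -0.045, -0.026 and -0.029 without 0Q replicate 1, 100Q replicate 2 or 100Q replicate 3. The list for the unfolded protein response of the endoplasmic reticulum had 0.030 (camera, Benjamini-Hochberg adjusted p = 0.882). For the proteasome (mean -0.013, median 0.0099, direction lower; 0.726) and immediate early genes (mean -0.0077, median 0.023, direction higher; 0.883) the mean, median and test differed in sign, as they did for the tRNA synthetases (median 0.0048, direction higher; camera, Benjamini-Hochberg adjusted p).

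Markers of other cell types did not pass in the fit of all libraries. Neuronal and adrenal lineage genes, which HEK293T cells express, had a mean of -0.10, with INA at -0.32 ± 0.12 (SE) and NEFL at -0.20 ± 0.10 (camera, Benjamini-Hochberg adjusted p = 0.0794). That mean rested on single libraries, at 0.0055 without 0Q replicate 1 (camera, Benjamini-Hochberg adjusted p = 0.618) and -0.20 without 0Q replicate 3, where the list passed (0.0133). Fibroblast markers had 0.11 over 3 tested genes (camera, Benjamini-Hochberg adjusted p = 0.612). Their mean was 0.042 without 0Q replicate 2, 0.18 without 100Q replicate 2 and 0.29 without 100Q replicate 3. Keratinized epithelium markers had -0.17 over 3 (0.883), from -0.32 without 100Q replicate 1 to -0.049 without 0Q replicate 1 (camera, Benjamini-Hochberg adjusted p). Monocyte and lymphocyte markers had fewer than 3 tested genes; PTPRC and LYZ, chosen after their values were seen, had 0 counts in all 6 libraries.

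The last comparison asked whether genes rich in codons read by queuosine tRNAs differed. Among 12163 tested genes with codon counts, 2 of 6 sets were called, both lower, and the adjusted p was 0.575 for all 6 with an estimated correlation (camera, Benjamini-Hochberg). The lowest 10% by the C-ending share of codons for tyrosine, histidine, asparagine and aspartate (1218 genes) had a mean log2 fold change of -0.039 (camera, Benjamini-Hochberg adjusted p = 0.0130). The lowest 10% by the C-ending share of phenylalanine and cysteine codons, which queuosine tRNAs do not read (1227 genes), had -0.033 (camera, Benjamini-Hochberg adjusted p = 0.0371). The C-ending shares of the queuosine and control codons went together across genes (Spearman's rho 0.799). Genes with the most queuosine codons had -0.035 (camera, Benjamini-Hochberg adjusted p = 0.134) and those with the fewest 0.038 (0.151). The highest 10% by C-ending share had 0.043 for queuosine codons (0.151) and 0.044 for control codons (0.151; camera, Benjamini-Hochberg adjusted p). Across genes, which are not independent replicates, Spearman's rho with the log2 fold change was 0.145 for the C-ending queuosine share, 0.130 for the control share and 0.175 for transcript GC content.

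C-ending codons add to GC content, so the GC and length correction would also remove a difference tied to codon use. It therefore cannot tell codon use from a technical GC trend. Both codon calls ended with this correction, at means of -0.00091 and 0.0028 (camera, Benjamini-Hochberg adjusted p = 0.804 and 0.915). Both were lost without 0Q replicate 2 (camera, Benjamini-Hochberg adjusted p = 0.0730 and 0.0825), 0Q replicate 3 (0.804 for both, with means of 0.00025 and -0.0039) or 100Q replicate 2 (0.720 for both, with means of -0.019 and -0.021). Without 100Q replicate 3 both were kept, with means of -0.064 and -0.065. Without 0Q replicate 1 all 6 sets passed, with means of -0.068 and -0.059 for the lowest C-ending queuosine and control sets, 0.087 and 0.091 for the highest, and -0.047 and 0.081 for genes with the most and the fewest queuosine codons. Without 100Q replicate 1 both highest C-ending sets passed as well (camera, Benjamini-Hochberg adjusted p = 0.0368 for both). With sets of 20% of genes the highest C-ending queuosine set passed (camera, Benjamini-Hochberg adjusted p = 0.0369).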

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

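The GC and length correction was chosen after seeing the data; the other alternatives were planned. Among 145 single genes, list means and codon sets, 1631 values under alternatives were compared: 1496 kept direction and side of the threshold, 64 kept direction but lost the call, 28 kept direction and gained one, and 43 changed direction. Depth limits genes with few counts most, since 100Q replicate 2 had 4023956 counts. ZACN was called in 10 of 15 gene fits and NEAT1 in 9. With no filter on low counts 71 genes were called (36 higher, 35 lower), with more genes tested; with the stricter filter, 1 (1 higher), with fewer; with DESeq2, 14 (10 higher, 4 lower); with limma-voom, 1 (1 higher). The GC and length correction gave 4 genes, 1 of them lower, and 0 codon sets, and the estimated correlation gave 0 lists and 0 codon sets. Leaving out 1 library, which tests fewer samples, gave 0 to 6 genes (0 to 2 higher, 0 to 4 lower), 4 to 14 lists and 0 to 6 codon sets; there were 0 genes without 0Q replicate 1, 0Q replicate 2 or 100Q replicate 1, and 6 genes and 4 lists without 100Q replicate 3. Of the 12 list calls, 3 (heat shock, long nuclear RNA and G2/M) were kept in all 6 of these fits, and the test's direction was kept for all 12. Except where fewer samples or another set of tested genes accounts for it, the cause was not tested.

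The replicate numbers share only a number: deviations of same-numbered libraries correlated at 0.0014, -0.020 and 0.081, and not every library correlated best with its own number. With the replicate block 3 genes (2 higher, 1 lower), 11 lists and 2 codon sets were called; the block gave NEAT1 an adjusted p of 0.0524 and the hypoxia list 0.0578 (edgeR quasi-likelihood test and camera, Benjamini-Hochberg), and turned GTDC1 to -0.0060 and RFXAP to -0.013.

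Results whose test changed direction were all uncalled in the fit of all libraries. The means of 3 called results changed sign while the test's direction was kept: 0.017 for structural RNAs and 0.00025 for the lowest C-ending queuosine set without 0Q replicate 3, and 0.0028 for the lowest C-ending control set with the GC and length correction. With DESeq2 RFXAP was -0.00079. With the GC and length correction, list means were -0.025 for immediate early, 0.0067 for secretory pathway, -0.0053 for MHC class I, 0.0089 for nuclear oxidative phosphorylation and 0.017 for proteasome genes, and 0.011 for genes with the fewest queuosine codons, -0.0027 for the highest C-ending queuosine and 0.0047 for the highest C-ending control share. Leaving out 1 library, log2 fold changes ran from -0.10 to 0.25 for HLA-DQB1, -0.16 to 0.12 for RFXAP, -0.30 to 0.21 for GTDC1, -0.29 to 0.12 for HLA-DMA, -0.95 to 0.52 for SNORD3B-1, -0.20 to 0.031 for QTRT2, -0.058 to 0.36 for HLA-DOA, -0.092 to 0.066 for RFXANK and -0.27 to 0.45 for EPCAM. List means ran from -0.099 to 0.17 for MHC class II, -0.045 to 0.10 for mitochondrially encoded, -0.020 to 0.014 for tRNA synthetase, -0.32 to -0.049 for keratinized epithelium, -0.039 to 0.026 for immediate early, -0.063 to 0.059 for MHC class I, -0.0041 to 0.050 for unfolded protein response, -0.079 to -0.0022 for nuclear oxidative phosphorylation and -0.036 to 0.020 for proteasome genes; the direction is that of the test, which can differ from the mean. The highest C-ending sets ran from 0.0071 to 0.087 (queuosine) and -0.00061 to 0.091 (control), and genes with the most and the fewest queuosine codons from -0.070 to -0.00088 and 0.016 to 0.081. Leaving out 1 library moved 51 of 105 uncalled genes, 19 of 20 uncalled lists and 4 of 4 uncalled codon sets by over 1.5 times or through 0.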

Other observations

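The test of ZACN with EXOC7 and the choice of the 3 mitochondrial genes below were made only after their values were seen, and the GC and length correction was added after the data were seen. The 13 mitochondrially encoded messenger RNAs were not called as a list, but were called higher with the GC and length correction (mean 0.13; camera, Benjamini-Hochberg adjusted p = 0.00023). MT-ATP8, MT-ATP6 and MT-CO3, neighbours on the mitochondrial genome (positions 8366 to 9990) that encode subunits of ATP synthase and cytochrome c oxidase, had the 3 lowest log2 fold changes of the 13, at -0.27 ± 0.12, -0.26 ± 0.10 and -0.16 ± 0.08 (SE). MT-ND5 had the highest, at 0.25 ± 0.09, and none of the 13 passed with edgeR, DESeq2 or limma-voom (3 at an unadjusted p under 0.05 with edgeR, 1 of them higher).

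Against the mean log2 CPM of the other 10, the 3 genes stood at 0.00051 ± 0.048 in 0Q and -0.33 ± 0.039 in 100Q (SD, n = 3 per group), a difference of -0.33 or 0.797-fold, with all 3 libraries of 100Q below those of 0Q. The exact permutation p of 0.1 (two-sided) is the smallest possible, and the 3 genes are 1 of 286 possible choices, so chance was not excluded. Reads shared with nuclear copies of mitochondrial DNA are argued against as the whole cause, since adding the counts of 404 such copies left the difference at -0.322 with the groups apart. Trends with GC content and length, as fitted, are argued against likewise, with -0.272 after their removal. The correction set the smallest lengths to a lower limit, so it may miss a trend among very short transcripts. A change in the processing or stability of this stretch with queuine may remain as a hypothesis, which was not tested.

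The values of ZACN may come from reads of EXOC7, a gene it overlaps. The summed count of both genes had a log2 fold change of -0.103 (95% interval -0.34 to 0.13), with 143 CPM in 0Q and 134 in 100Q, while EXOC7 alone was at 143 and 118 CPM (-0.29, -0.52 to -0.057). The sum thus shows no excess of reads over the locus in 100Q, as reassigned reads predict. However, the 16.27 CPM of ZACN in 100Q is within the spread of the sum (SD 18.91 in 0Q and 16.45 in 100Q). A rise of ZACN alone could therefore go unseen in the sum, which does not decide the question. Genes with an unadjusted p under 0.001 overlapped another tested gene in 16 of 19 cases (84.2%), against 39.5% of the others (1 further such gene, absent from the annotation used, could not be placed), an odds ratio of 8.17 (95% interval 2.34 to 43.8; one-sided Fisher's exact p = 8.52e-05). ZACN is itself among these genes, and overlapping genes that share reads are not independent, so this interval and p may overstate the evidence. A transcript of ZACN made with queuine, or a change in the splicing of the locus, remains open and was not tested.

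Opposite values also appeared at the loci below, in genes chosen after their values were seen. Values of the partners of the other overlapping genes are not reported here, so this does not show how common the pattern is. TBCE had a log2 fold change of 0.60 ± 0.13 (SE) where ENSG00000285053, annotated across it, had -1.07 ± 0.18, and RPS10-NUDT3 had 0.63 ± 0.17 where NUDT3 had -0.71 ± 0.14. Neither TBCE nor RPS10-NUDT3 passed with edgeR at the default filter. With no filter on low counts edgeR called both (quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00291 and 0.0193), and DESeq2 called TBCE (Benjamini-Hochberg adjusted p = 0.0108).

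NEAT1 overlaps no other tested gene. Its log2 fold change was 0.509 (95% interval 0.35 to 0.67) after removal of GC and length trends, against 0.53 before. This argues against the trends as fitted being its whole cause. Because the correction set the greatest lengths to an upper limit, it may miss a length trend specific to transcripts as long as NEAT1. A response to queuine may remain, as do differences in the recovery of nuclear RNA between cultures, which were not tested.

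Other splits of the 6 libraries into 3 and 3 were counted. The real grouping gave 2 genes and the highest other split 4, and 9 of the 10 splits gave as many genes. For lists the real grouping gave 12 and the highest other 9 (1 of 10 splits as many), and for codon sets 2 against 6 (4 of 10). With 10 splits, no share under 0.05 can be reached.

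The noncoding genes ENSG00000281181, ENSG00000280800 and ENSG00000280614 on chromosome 21, chosen after their values were seen, together took 4.57% to 6.04% of the counts of each library. Their single shares varied between libraries of a group, from 1.52% to 3.11% for ENSG00000281181 in 100Q.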
